A study of Rattus norvegicus with 4 samples.

How the data were processed

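RNA abundance was measured in pancreatic islets of Sprague Dawley rats at postnatal day 14. The 4 samples with intrauterine growth restriction (IUGR) came from pregnancies in which both uterine arteries were ligated at embryonic day 18, and the 4 control samples came from sham-operated pregnancies. Amplified cDNA from total RNA was labelled with Cy3 or Cy5, and 1 IUGR sample and 1 control sample were hybridised together to each of 4 arrays on 1 slide. Arrays 1 and 2 carried IUGR in Cy5, and arrays 3 and 4 carried IUGR in Cy3. Array 1 held IUGR replicate 2 with control replicate 1, array 2 held IUGR replicate 1 with control replicate 2, array 3 held IUGR replicate 4 with control replicate 3, and array 4 held IUGR replicate 3 with control replicate 4. The labels do not give the sex of the pups, the number of animals per sample or their litters.

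Per the file headers, the scanner values were extracted with Agilent Feature Extraction 10.10.1.1 under protocol GE2_1010_Sep10 for array design 28282. The deposited scanner files hold mean signals, median local backgrounds and processed signals, all in units of intensity (pixel brightness). They also hold a deposited log10 ratio of the processed Cy5 over Cy3 signals, and other deposited columns that are flags. The deposited value table holds a log2 ratio per spot, whose direction and normalization the labels do not state. Checked against the scanner values, its 43030 values per array were log2 ratios of Cy5 over Cy3 with medians between -0.029 and 0.008. Averaged by probe, they correlated with loess-normalized signals without background subtraction at r from 0.986 to 0.998 across probes. The notes of the authors name limma without a version or settings.

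The arrays carried 42877 spots of 30367 probes, each 60 bases long, and 1377 control spots. A probe had up to 10 spots. Gene names, and probe coordinates on the rat assembly rn4, came from the scanner files. By accession, 17998 probes (59.3%) matched a RefSeq gene table of assembly GRCr8, which was used for names only.

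Mean signals and median local backgrounds were processed in R 4.3.3 with limma 3.58.1 and statmod 1.5.0. Background was corrected with normexp and an offset of 50, and each array was normalized by loess with control spots at weight 0. Spots marked as feature outliers were left out, and replicate spots of a probe were averaged. Ratios were turned to IUGR over control. The probe with the highest mean intensity stood for each gene. A gene was tested if it was measured on all 4 arrays and was well above background in at least 2 of the 4 IUGR channels or at least 2 of the 4 control channels, which left 20035 genes or unnamed probes, 13585 of them with a gene symbol. Of these, 2672 genes had more than 1 probe that passed.

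The lists, the filter, the tests and the rule for named genes were fixed before the data were examined, with 1 exception. Spots with an outlying local background (222, 44, 145 and 52 spots on arrays 1 to 4) were given the median background of their array and channel. That choice was made after the data were seen, because leaving such spots out removed the bright insulin genes Ins1 and Ins2 from the test. Leaving them out and keeping them as measured were both run as alternatives.

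The limma model held a dye term and the IUGR over control contrast, with 2 residual degrees of freedom per gene and 2.75 prior degrees of freedom. The SE given with each gene ratio is the moderated SE of this model, with the dye difference taken out. It can be far smaller than the spread of the 4 array ratios, and is not comparable with the SD of list means over arrays, which keeps the dye difference. Calls were made at a Benjamini-Hochberg adjusted p under 0.05. Gene lists with at least 5 tested genes were tested with limma's camera at a preset correlation of 0.01, adjusted over 35 lists. Camera with an estimated correlation was run beside it. So was fry, whose directional p asks whether the genes of a list move on balance one way and whose mixed p asks whether they change in either direction. The rule for named genes took up to 10 called genes per direction with the same sign on all arrays, or up to 5 per direction by p where fewer passed. It also took a fixed set of genes, among them Ins1, Ins2, Gcg, Sst, Ppy, Pdx1, Mafa, Slc2a2, Iapp, Il4, Il13 and Vegfa, and from each list up to 4 called members or, with none called, the 2 with the smallest p.

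The gene test was tested on simulated data with 20035 genes. It recovered 43 of 67 genes (64.2%) shifted by a log2 ratio of 1, 92.5% of those shifted by 2 and 93.9% of those shifted by 3, with 10 false calls among 177. All these genes were shifted in the same run, which loosens the Benjamini-Hochberg cutoff. The simulated noise was independent between genes and arrays, whereas the real arrays shared patterns across genes. These shares are thus not the power of the real test. A simulated list shifted by 0.5 had a camera adjusted p of 2.97e-23 with the preset correlation and 0.286 with an estimated correlation. The estimated correlation thus missed a known shift at this number of arrays. The simulated genes were independent, so the preset correlation of 0.01 was not checked on correlated members. Among the called lists of the real data, estimated correlations ran from 0.088 (insulin secretion machinery) to 0.80 (acinar), with 0.59 for T and NK cell markers. There the p of the preset test can be too small.

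Alternatives covered background correction, within-array and between-array normalization, Agilent's processed signals, the deposited ratios, the filter on dim probes, the dye term, the prior of limma, array weights, the choice of probe, the threshold, a separate-channel fit, a block by replicate number and leaving out each array. A further alternative, chosen after the data were seen, added the log2 Cy5 over Cy3 brightness of each array as a covariate. Control spots were not tested. For arrays, the number of arrays limits the precision of each value: the median standard error of a log2 ratio was 0.09.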

Results

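Islet RNA from 4 IUGR and 4 control samples at postnatal day 14 was compared on 4 two-colour arrays, each holding 1 sample of either group. The median signal of the IUGR channel was 344, 105, 154 and 199.8 intensity units on arrays 1 to 4, and that of the control channel was 107, 314, 823 and 586. Of the probes, 73.9%, 61.8%, 68.3% and 66.5% were well above background in the IUGR channel and 67.3%, 74.2%, 75.4% and 77.2% in the control channel. No spot was saturated (0 on each array). The IUGR channel was brighter than the control channel on array 1, by a log2 ratio of 1.68, and dimmer on arrays 2, 3 and 4, at -1.58, -2.42 and -1.55. Across genes, which are not independent replicates, the normalized IUGR over control ratios of arrays 2, 3 and 4 correlated with one another at r = 0.63 (arrays 2 and 3), 0.37 (arrays 2 and 4) and 0.63 (arrays 3 and 4). The ratios of array 1 correlated with those of arrays 2, 3 and 4 at r = 0.13, -0.23 and -0.30.

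**Figure D1:**
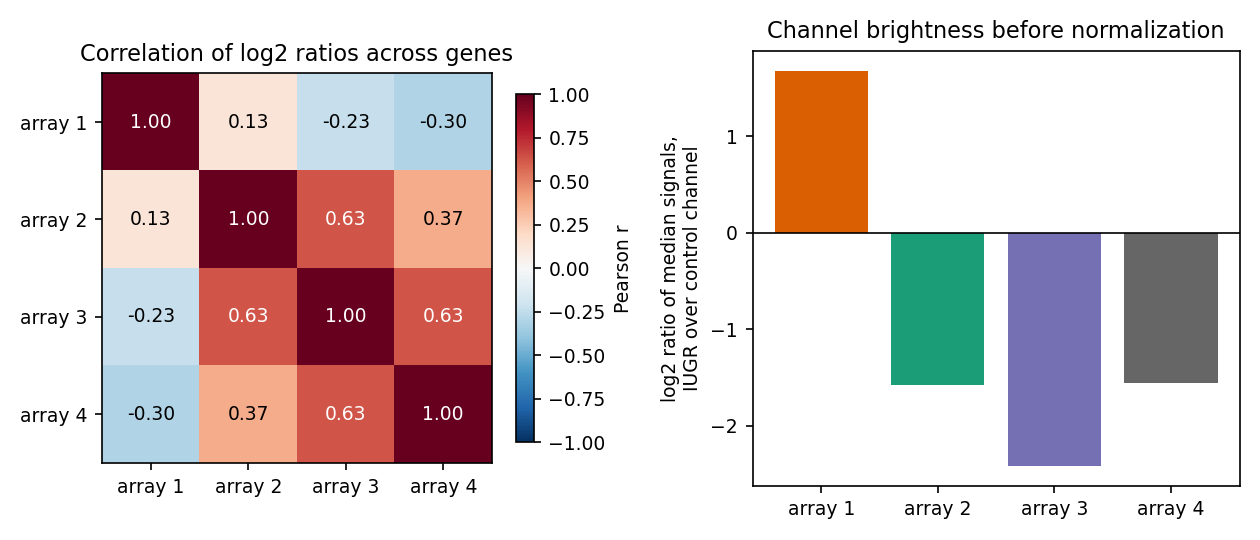
The left panel shows Pearson's r across 20035 genes between the log2 IUGR over control ratios of each pair of arrays, and the right panel shows the log2 ratio of the median IUGR signal to the median control signal before normalization. Array 1 has the only bar above 0 (1.68) and r from -0.30 to 0.13 with the other arrays.

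Which genes differ between IUGR and control islets at postnatal day 14 was the question of the main comparison, and the 5 genes with the smallest p in each direction, among those with a gene symbol, included regulators of tissue patterning and immune signals. Ccl21, a chemokine that guides T cells and dendritic cells into lymphoid tissue, had a log2 IUGR over control ratio of -1.61 ± 0.14 (moderated limma SE with the dye difference taken out, n = 4 arrays). Its probe was A_44_P178252 at 59239182 to 59239241 on chromosome 5 of rn4. Grem1, a secreted antagonist of bone morphogenetic proteins, had -1.58 ± 0.13 (A_44_P256301 at 99597201 to 99597242 on chromosome 3). The T-box transcription factor Tbx1 had -1.26 ± 0.09 (chromosome 11), the gut and islet hormone gene Ghrl (ghrelin) had -0.97 ± 0.09 (chromosome 4) and the neurexin ligand Nxph1 had -0.90 ± 0.08 (chromosome 4). The Ghrl ratios on arrays 1 to 4 were -0.50, -0.30, -1.67 and -1.39, with an SD of 0.67. In the other direction, the myeloid receptor Trem2 had 1.00 ± 0.08 (A_42_P512838 at 8059065 to 8059124 on chromosome 9), the macrophage lectin Clec10a had 0.85 ± 0.09 (chromosome 10), the microfibril gene Mfap5 had 0.97 ± 0.12 (chromosome 4) and the cytokine gene Tnf had 0.66 ± 0.09 (chromosome 20). Defa10, of the alpha-defensin family of antimicrobial peptides, had 1.55 ± 0.20 (A_64_P125531 at 75304742 to 75304801 on chromosome 16), with ratios of 0.34, 0.96, 1.99 and 2.92 on arrays 1 to 4.

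These 10 genes had the same sign on all 4 arrays, but each had a limma adjusted p of 0.339, the smallest of the test. Limma called 0 genes higher and 0 lower in IUGR among 20035 tested. At an unadjusted p under 0.05 there were 2737 genes, 1427 higher and 1310 lower, where 1001.75 would be met by chance if genes were independent, which they are not. All 4 arrays gave 1 sign in 4142 genes (20.7%), where chance gives 12.5% if the arrays are independent. Arrays 2, 3 and 4, which shared a dimmer IUGR channel, correlated with one another at r from 0.37 to 0.63. That correlation raises the share whatever its cause, so the excess is no separate evidence of a change with IUGR. Leaving out 1 array kept the count of calls at 0, but the number at an unadjusted p under 0.05 was 6215 without array 1, 935 without array 2 and 465 without array 3. Normalization by median centring in place of loess called 15 genes, all lower in IUGR, among them Ccl21 (-1.99, adjusted p = 0.0121) and Grem1 (-1.70, adjusted p = 0.0286), and channel brightness as a covariate, added after the data were seen, called 7, all lower, among them Ccl21 (-1.40, adjusted p = 0.0453) and Tbx1 (-1.17, adjusted p = 0.0470).

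**Figure D2:**
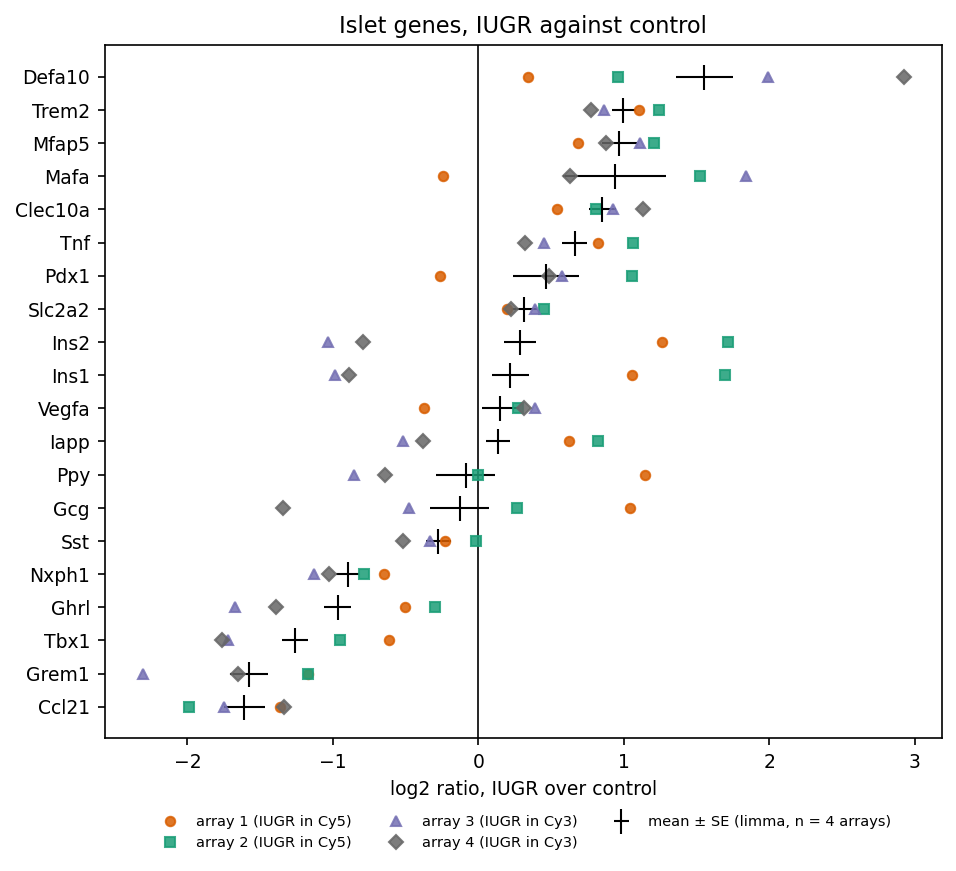
Log2 ratio of IUGR over control (x axis) for the 5 named genes with the smallest p in each direction and for islet genes chosen in advance, with 1 point per array. In black is the limma mean over 4 arrays ± its moderated SE, with the dye difference taken out. Ccl21 (-1.61) and Trem2 (1.00) keep 1 sign on all arrays, while Ins1 is above 0 on arrays 1 and 2 (1.06 and 1.70) and below 0 on arrays 3 and 4 (-0.98 and -0.89).

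Among the islet hormone genes, Ins1, Ins2, Iapp and Gcg had opposite signs in the dye orientations. Ins1 had log2 ratios of 1.06, 1.70, -0.98 and -0.89 on arrays 1 to 4, and Ins2 had 1.26, 1.72, -1.03 and -0.79, so both were brighter in Cy5 whichever sample carried it. Their mean ratios were 0.22 ± 0.13 and 0.29 ± 0.11 (SE, n = 4 arrays), and with median centring -0.18 and -0.12. Iapp, which encodes the amyloid peptide secreted with insulin, had 0.62, 0.82, -0.52 and -0.38 on arrays 1 to 4, a mean of 0.14 ± 0.08, and -0.27 with median centring. Gcg (glucagon) had 1.04, 0.27, -0.48 and -1.34, with a mean of -0.13 ± 0.20. That mean was 0.067 without array 2, 0.090 without array 4, 0.024 with channel brightness as a covariate and -0.54 with median centring. Sst (somatostatin) had -0.27 ± 0.09, and -0.67 with median centring. Ppy (pancreatic polypeptide) had -0.09 ± 0.20, with the other of 2 probes of opposite sign. Its mean was 0.20 without array 2, 0.047 with outlying backgrounds left out, 0.25 with channel brightness as a covariate and -0.51 with median centring. Of the beta cell transcription factors, Mafa had 0.94 ± 0.36 and Pdx1 0.47 ± 0.23, with ratios above 0 on arrays 2, 3 and 4 and below 0 on array 1 (-0.24 and -0.26). Without array 2 the mean was 0.50 for Mafa and 0.14 for Pdx1, and without array 1 it was 1.38 and 0.80; with channel brightness as a covariate it was 0.36 and 0.094. The glucose transporter gene Slc2a2 had 0.32 ± 0.09 and was positive on all 4 arrays, and -0.06 with median centring. The angiogenic factor Vegfa had 0.15 ± 0.13, and -0.21 with median centring, -0.0096 without array 2 and -0.032 with channel brightness as a covariate. None of these genes passed the limma test, with adjusted p from 0.339 (Ins2) to 0.819 (Ppy). The type 2 cytokine genes Il4 and Il13 had 1 probe each, which was well above background in 0 IUGR channels and 1 control channel, and were not tested.

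Gene lists fixed in advance moved in both directions, and camera called 11 of 35, 5 higher and 6 lower in IUGR. With an estimated correlation camera called 0 lists (0 at an unadjusted p under 0.05), and fry called 0 in its directional test (3 at an unadjusted p under 0.05, smallest adjusted p = 0.201). Those 3 were glycolysis, macrophage markers, and mitochondrial biogenesis and uncoupling, which are not among the 11 lists that camera called. The mixed test of fry called 2, the delta, PP and epsilon cell markers and the fibroblast and stellate cell markers, each with an adjusted p of 0.0247.

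Lymphocyte genes were lower in IUGR islets. Of 15 T and NK cell markers tested, 14 were lower, with a mean log2 ratio of -0.52 ± 0.54 (SD, n = 4 arrays) and array means of 0.04, -0.29, -1.24 and -0.58. The list fell with an adjusted p of 1.55e-06, or an adjusted p = 0.832 with an estimated correlation. Among all genes 0 members passed the limma test (10 at an unadjusted p under 0.05), and 8 did when adjusted over the list alone. The T cell receptor chain gene Cd3d had -1.04 ± 0.20 (SE, n = 4 arrays) and the cytotoxic granule gene Nkg7 had -0.45 ± 0.07. Of 8 B cell markers, 6 were lower, with a mean of -0.34 ± 0.46 (SD) and array means of 0.14, -0.08, -0.87 and -0.54, and the list fell with an adjusted p of 0.00904 (adjusted p = 0.832 with an estimated correlation; 4 members passed when adjusted over the list alone). The B cell receptor component gene Cd79b had -1.05 ± 0.18. The call of the B cell list ended with median centring (adjusted p = 0.196), with outlying backgrounds kept as measured (0.198) and with samples blocked by replicate number (0.0541).

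Red blood cell, granulocyte and mast cell genes were higher. All 6 red blood cell markers tested were above 0, with a mean of 0.53 ± 0.97 (SD, n = 4 arrays) and array means of -0.63, 0.12, 1.47 and 1.16. Their list rose with an adjusted p of 0.00164 (adjusted p = 0.832 with an estimated correlation; 2 members passed when adjusted over the list alone). The beta globin gene Hbb had 0.63 ± 0.12 (SE) and Alas2, the first enzyme of haem synthesis in red cells, had 0.60 ± 0.13. All 10 granulocyte and mast cell markers tested were above 0, with a mean of 0.55 ± 0.76 (SD) and array means of -0.56, 0.78, 1.18 and 0.80. That list rose with an adjusted p of 0.00872 (adjusted p = 0.832 with an estimated correlation; 0 members passed when adjusted over the list alone, 3 at an unadjusted p under 0.05). The mast cell protease gene Cpa3 had 0.86 ± 0.23 and the IgE receptor subunit gene Ms4a2 had 0.33 ± 0.10. Without array 2 the granulocyte and mast cell list was no longer called (mean 0.22, adjusted p = 0.127) and the red blood cell mean was 0.34, and without array 1 the granulocyte and mast cell mean was 0.88. The red blood cell call ended with median centring (adjusted p = 0.362), and the granulocyte and mast cell call ended with channel brightness as a covariate (adjusted p = 0.128).

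Immediate early and heat shock genes, which respond to handling and stress, were lower in 13 of 15 members, with a mean of -0.39 ± 0.25 (SD, n = 4 arrays). The list fell with an adjusted p of 6.7e-04 (adjusted p = 0.832 with an estimated correlation; 6 members passed when adjusted over the list alone). Fos had -0.93 ± 0.16 (SE) and the orphan nuclear receptor gene Nr4a1 had -0.48 ± 0.08. Duct cell markers were lower in 10 of 12 members, with a mean of -0.30 ± 0.19 (SD), and the list fell with an adjusted p of 0.00524 (adjusted p = 0.832 with an estimated correlation; 2 members passed when adjusted over the list alone). The duct keratin gene Krt19 had -0.64 ± 0.10 and the chloride channel gene Cftr had -1.05 ± 0.24. Without array 2 the duct mean was -0.19.

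Delta, PP and epsilon cell markers were lower in 7 of 8 members, with a mean of -0.35 ± 0.49 (SD, n = 4 arrays) and array means of 0.29, -0.26, -0.88 and -0.55. The list fell with an adjusted p of 0.00692 (adjusted p = 0.832 with an estimated correlation; 1 member passed when adjusted over the list alone). Besides Ghrl, the calcium-sensing receptor gene Casr had -0.30 ± 0.09 (SE). The call ended without array 2 (mean -0.21, adjusted p = 0.0509) and with channel brightness as a covariate (adjusted p = 0.0906). Schwann and neural cell markers were lower in 6 of 7 members, with a mean of -0.37 ± 0.25 (SD) and an adjusted p of 0.00872 (adjusted p = 0.832 with an estimated correlation; 0 members passed when adjusted over the list alone, 2 at an unadjusted p under 0.05). The myelin gene Mbp had -0.66 ± 0.24 (SE), with the other of 2 Mbp probes of opposite sign. Its ratios were -0.92, -0.13, -1.37 and -0.21 on arrays 1 to 4, and its mean ranged from -0.95 to -0.37 over the alternatives. Without array 1 the Schwann and neural list was not called (adjusted p = 0.117), and without array 3 its mean was -0.22.

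The insulin secretion machinery was higher in 14 of 19 members, with a mean of 0.24 ± 0.17 (SD, n = 4 arrays). The list rose with an adjusted p of 0.00872 (adjusted p = 0.832 with an estimated correlation; 0 members passed when adjusted over the list alone, 6 at an unadjusted p under 0.05). The vesicle GTPase gene Rab3a had 0.41 ± 0.08 (SE) and the vesicle priming gene Unc13a had 0.71 ± 0.21. Unc13a had -0.10, 0.98, 1.23 and 0.74 on arrays 1 to 4, and its mean ranged from 0.38 to 1.06 over the alternatives. The call ended with median centring (adjusted p = 0.779), and without array 2 the mean was 0.15. Beta cell genes were above 0 in 14 of 19 members, with a mean of 0.23 ± 0.25 (SD), and were not called (adjusted p = 0.0642). It was called without array 1 (mean 0.37, adjusted p = 0.00747), without array 4 (mean 0.28, adjusted p = 0.0474), with array weights (adjusted p = 0.0471) and with samples blocked by replicate number (adjusted p = 0.00680). The beta cell mean was 0.10 without array 2 (adjusted p = 0.143), 0.072 with channel brightness as a covariate (adjusted p = 0.245) and -0.086 with median centring (adjusted p = 0.550). The incretin receptor gene Glp1r had 0.35 ± 0.11.

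Acinar cell markers, the digestive enzymes of the exocrine pancreas, were higher in 22 of 23 members, with a mean of 0.40 ± 0.82 (SD, n = 4 arrays) that rested on array 3 and was -0.0018 with median centring. The array means were 0.36, -0.08, 1.56 and -0.26. The list rose with an adjusted p of 0.0113 (adjusted p = 0.858 with an estimated correlation; 0 members passed when adjusted over the list alone, 1 at an unadjusted p under 0.05), but without array 3 its mean was -0.057 (adjusted p = 0.370), without array 1 it was not called (adjusted p = 0.407), and without array 4 its mean was 0.85. The amylase gene Amy2a3 had 1.16 ± 0.52 (SE), with 3.28 on array 3, and the acinar transcription factor gene Bhlha15 had 0.38 ± 0.09. Genes of ER stress and protein folding were higher in 20 of 24 members, with a mean of 0.18 ± 0.22 (SD), array means of -0.08, 0.41, 0.30 and 0.10, and a mean of -0.075 with median centring. Their list rose with an adjusted p of 0.0405 (adjusted p = 0.832 with an estimated correlation; 0 members passed when adjusted over the list alone, 2 at an unadjusted p under 0.05). The members with the smallest p went the other way, the chaperone gene Hsp90b1 at -0.23 ± 0.08 and the stress-induced transcription factor gene Atf3 at -0.46 ± 0.16. Without array 2 the ER list was not called (mean 0.06, adjusted p = 0.348), nor without array 3 (adjusted p = 0.0615), and without array 1 its mean was 0.31. Among the other settings, its call ended with an offset of 0 (adjusted p = 0.0529), Agilent's processed signals (0.0718), the strict filter (0.120), the deposited ratios (0.0577) and channel brightness as a covariate (0.679).

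**Figure D3:**
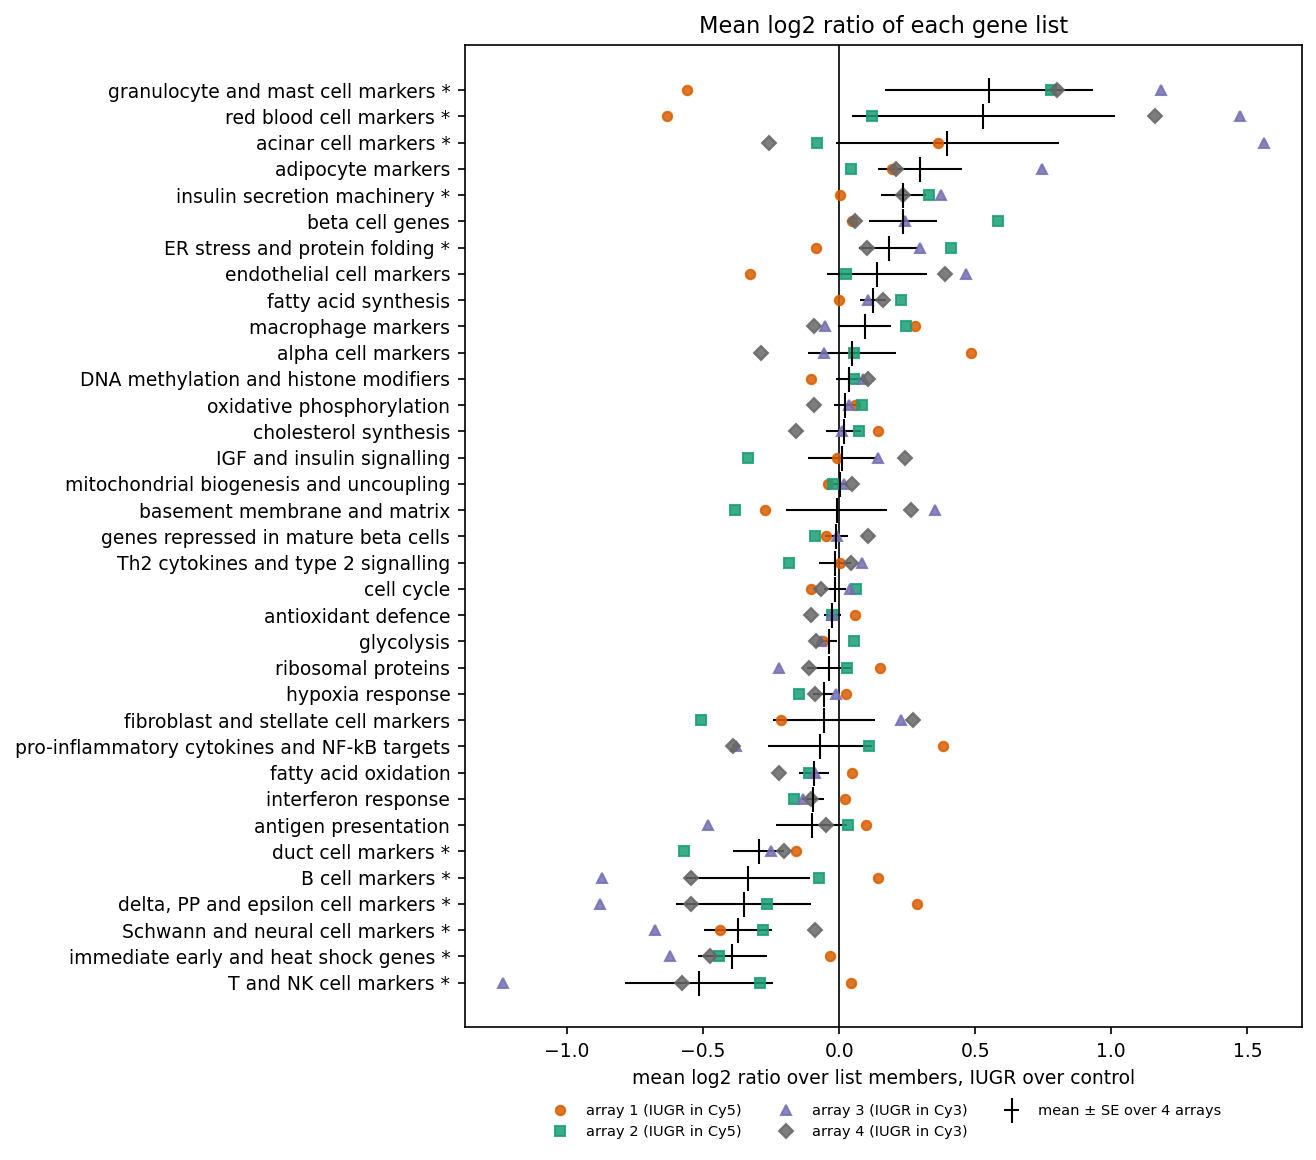
Mean log2 ratio of IUGR over control over the members of each gene list (x axis), with 1 point per array and the mean ± SE over 4 arrays in black, and an asterisk at the 11 lists past the threshold of camera with the preset correlation. The acinar mean of 1.56 on array 3 and the T and NK cell mean of -1.24 on array 3 stand at the ends of the range.

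Inflammatory gene groups were not called, though single members had sizeable ratios. Macrophage markers had a mean of 0.09 (adjusted p = 0.304), with the haemoglobin scavenger receptor gene Cd163 at 0.89 ± 0.14 (SE, n = 4 arrays) and the lysozyme gene Lyz2 at -0.68 ± 0.12, and 6 of 17 members passed when adjusted over the list alone. Pro-inflammatory cytokines and NF-kB targets had a mean of -0.07 (adjusted p = 0.242), with Il18 at -0.65 ± 0.10 beside Tnf, and 3 of 19 passed when adjusted over the list alone. The array means of that list were 0.38, 0.11, -0.38 and -0.39, with opposite signs in the dye orientations. Th2 cytokines and type 2 signalling genes had a mean of -0.01 (adjusted p = 0.924), with the eosinophil chemokine gene Ccl11 at 0.58 ± 0.09 and the arginase gene Arg1 at 0.34 ± 0.08, and 4 of 12 passed when adjusted over the list alone. Interferon response genes had a mean of -0.10 (adjusted p = 0.105), with Rsad2 at 0.40 ± 0.11 and Ddx58 at -0.44 ± 0.13. Antigen presentation genes had a mean of -0.10 (adjusted p = 0.351), with the class II gene RT1-Da at -0.72 ± 0.21 and the peptide transporter gene Tap2 at 0.95 ± 0.28, and were called without array 4 (mean -0.21, adjusted p = 0.0220).

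Among the remaining cell types, adipocyte markers had a mean of 0.30 (adjusted p = 0.0939), with Cfd at 0.74 ± 0.14 (SE, n = 4 arrays) and Fabp4 at 0.55 ± 0.11, and 2 of 6 passed when adjusted over the list alone. That list was called without array 2 (mean 0.34, adjusted p = 0.00448), without array 4 (mean 0.43, adjusted p = 0.0191) and with channel brightness as a covariate (adjusted p = 0.00393). Endothelial cell markers had a mean of 0.14 (adjusted p = 0.469), with Emcn at 0.36 ± 0.10 and Vwf at -0.31 ± 0.09, where 1 of 3 Vwf probes had the opposite sign. Fibroblast and stellate cell markers had a mean of -0.06 (adjusted p = 0.914), with the smooth muscle actin gene Acta2 at -0.73 ± 0.11 and the matrix gene Postn at 0.44 ± 0.09, and 4 of 15 passed when adjusted over the list alone. With median centring that list was called lower (mean -0.38, adjusted p = 0.00843). After loess, the fibroblast and stellate array means were -0.21, -0.51, 0.23 and 0.27, with opposite signs in the dye orientations. Alpha cell markers had a mean of 0.05 (adjusted p = 0.795), with Ttr at 0.61 ± 0.17. Ttr had 1.30, 0.35, 0.30 and 0.51 on arrays 1 to 4, and its mean ranged from 0.26 to 0.89 over the alternatives. Genes repressed in mature beta cells had a mean of -0.01 (adjusted p = 0.914), with Ldha at -0.35 ± 0.08 and the hexokinase gene Hk1 at -0.36 ± 0.09.

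Metabolic and growth lists had means from -0.09 to 0.12 after loess, but with median centring the oxidative phosphorylation list (mean -0.34, adjusted p = 7.32e-04) and the glycolysis list (mean -0.38, adjusted p = 0.00555) were called lower. Oxidative phosphorylation genes had a mean of 0.02 (adjusted p = 0.914), with Uqcrc2 at -0.66 ± 0.21 (SE, n = 4 arrays) and Uqcrc1 at 0.46 ± 0.17, both of respiratory complex III. Both were largest on array 2 (-1.31 and 0.89). Over the alternatives Uqcrc2 ranged from -1.02 to -0.32 and Uqcrc1 from 0.12 to 0.67. Mitochondrial biogenesis and uncoupling genes had a mean of 0.0018 (adjusted p = 0.914), with Ppargc1b at 0.20 ± 0.08 and Polg at 0.21 ± 0.08. Glycolysis genes had a mean of -0.04 (adjusted p = 0.194), with Pfkp at -0.31 ± 0.08, and hypoxia response genes a mean of -0.06 (adjusted p = 0.914), with Egln3 at -0.37 ± 0.09 and P4ha1 at -0.40 ± 0.12. Antioxidant defence genes had a mean of -0.02 (adjusted p = 0.691), with Srxn1 at 0.30 ± 0.08 (-0.033 with median centring) and Gclc at -0.44 ± 0.15. Fatty acid oxidation genes had a mean of -0.09 (adjusted p = 0.190), with Angptl4 at -0.49 ± 0.08 and Cpt1a at 0.32 ± 0.09, and 1 of 15 passed when adjusted over the list alone. Fatty acid synthesis genes had a mean of 0.12 (adjusted p = 0.727), with Elovl6 at -0.50 ± 0.16 and Acaca at 0.63 ± 0.21, and cholesterol synthesis genes a mean of 0.02 (adjusted p = 0.835), with Fdft1 at 0.27 ± 0.12 and Lss at 0.23 ± 0.10 (-0.079 and -0.10 with median centring).

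IGF and insulin signalling genes had a mean of 0.01 (adjusted p = 0.565), with the fetal growth factor gene Igf2 at 0.30 ± 0.08 (SE, n = 4 arrays; -0.063 with median centring) and Igfbp2 at 0.38 ± 0.10. Basement membrane and matrix genes had a mean of -0.01 (adjusted p = 0.691), with Lama5 at -0.29 ± 0.08 and the protease inhibitor gene Timp1 at -0.33 ± 0.11. The array means of that list were -0.27, -0.38, 0.35 and 0.26, with opposite signs in the dye orientations. Cell cycle genes had a mean of -0.02 (adjusted p = 0.433), with Bub1b at -0.25 ± 0.09 and Pcna at -0.42 ± 0.16, and were called without array 2 (mean -0.06, adjusted p = 0.0287) and with channel brightness as a covariate (adjusted p = 0.00847). DNA methylation and histone modifiers had a mean of 0.04 (adjusted p = 0.914), with the histone methyltransferase gene Ezh2 at -0.21 ± 0.08 and Hdac1 at 0.31 ± 0.12 (-0.042 with median centring), where 2 of 3 Hdac1 probes had the opposite sign. Ribosomal protein genes had a mean of -0.04 (adjusted p = 0.433), with Rpl10a at -0.35 ± 0.09 and Rpl6 at 0.23 ± 0.09 (-0.17 with median centring), where 1 of 2 Rpl6 probes had the opposite sign, and with median centring the list was called lower (mean -0.44, adjusted p = 6.77e-05). The median and mean, or the mean and the direction of the test, differed in sign in 4 of the lists not called, those of hypoxia, mitochondrial biogenesis, genes repressed in mature beta cells and oxidative phosphorylation. The list members named for these groups had limma adjusted p of 0.339 each, and 0 were called.

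The dye term of the same limma model measured probes that favoured Cy5 or Cy3. The insulin genes were among the genes brighter in Cy5, with a log2 Cy5 over Cy3 difference of 1.16 for Ins1 and 1.20 for Ins2. Defa10 favoured Cy3, at -0.90. Of 87 named genes, 9 had 1 sign on arrays 1 and 2 and the other on arrays 3 and 4, namely Ins1, Ins2, Gcg, Iapp, Vwf, Atf3, Igf2, Lama5 and Rpl6. Limma called 0 genes for the dye (1843 at an unadjusted p under 0.05, smallest adjusted p = 0.502), and the SD of the dye differences across genes was 0.182, against 0.266 for the IUGR over control ratios.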

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

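The test of platelet genes, and the test of other assignments for the lists, were chosen before their results were seen. The other tests here were chosen after the results were seen, as were the added lists of lymphoid stroma, platelet, smooth muscle and defensin genes.

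In 4 of 122 named genes and lists, 1 array stood apart from the other 3 by a gap that is large against the range, where about 6.1 would by chance. The gap as a share of the range was 0.845 for Vegfa (array 1 at -0.37), 0.831 for the scavenger receptor gene Cd163 (array 1 at 0.34), 0.833 for the oxygen-sensing hydroxylase gene Egln3 (array 1 at -0.13) and 0.909 for Timp1 (array 2 at -0.72).

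Array 1 correlated with array 3 at r = -0.23 and with array 4 at r = -0.30 across 20035 genes. Its slope on the IUGR over control difference of arrays 2 to 4 was -0.134 (-0.219 to -0.0404 over 4 groups of genes by intensity), smaller in size than the -0.351 that exchanged IUGR and control samples on array 1 would give and the -0.427 of unequal channel brightness as the whole cause, but both sizes come from array 4 alone, so neither is excluded. Dye bias shared by the 4 arrays is a candidate explanation. Array 1 had a slope of 0.596 on the dye difference of arrays 2 to 4 (0.380 to 0.749 over these groups). That difference sets array 2 against arrays 3 and 4, so the sign of the slope largely restates the correlations already seen and is no separate evidence. Dim probes were also considered and set aside, since in the 5009 brightest genes array 1 still correlated with arrays 2, 3 and 4 at r = 0.26, -0.17 and -0.44. Turning array 1 gave 5275 genes at an unadjusted p under 0.05 against 2737 for the real assignment (0 called in both), which follows from its negative correlations and does not tell exchanged samples, channel brightness and dye bias apart, and a biological difference between the samples of array 1 and the others was not tested.

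T, NK and B cell genes were lower in IUGR on arrays 3 and 4 (T and NK cell means -1.24 and -0.58). Fewer non-islet cells of every type in the IUGR samples would lower all markers of other cells. In 4 of 7 lists of other cell types the mean over arrays 2 to 4 was above 0 by more than 2 standard errors. Those were taken over list members, which are not independent replicates, and the acinar list among them rested on array 3 (-0.08, 1.56 and -0.26). The granulocyte and mast cell list (0.78, 1.18 and 0.80) and the red blood cell list (0.12, 1.47 and 1.16) were above 0 on each of these arrays. On array 1, which is left out here, both lists were below 0 (-0.56 and -0.63). Dye bias stays open for the red blood cell list. With the dye difference taken out, the granulocyte and mast cell mean over 4 arrays was within 2 standard errors of 0. A loss of every cell type is thus not excluded. The duct list was below 0, at -0.34. Lymphoid tissue among the control islets may have added the T, NK and B cell genes. The lymphoid stroma genes, listed without Glycam1, Ccl21 and Ccl19 because these were seen first, had a median of -0.17 (standard error 0.0848) over arrays 2 to 4. That median was above the cutoff set for lymphoid tissue by more than this standard error, which went against the explanation. Only 12 of 16 of the lymphoid stroma genes (75%) were tested, under the share set for a valid check, so lymphoid tissue stays open. Glycam1, a mucin of lymph node vessels, had -2.62 ± 0.30 and the lymphoid chemokine gene Ccl19 had -1.44 ± 0.14 (SE, n = 4 arrays), both chosen after their values were seen. A difference in lymphocytes between IUGR and control islets was not tested apart from these and stays open.

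Granulocyte and mast cell genes were higher in IUGR on arrays 2, 3 and 4, and red blood cell genes on arrays 3 and 4 (array 2 at 0.12), and both lists were below 0 on array 1. A dye bias alike on all arrays cancels between the dye orientations. The red blood cell list had a log2 Cy5 over Cy3 difference of -0.787, and with it taken out the mean was 0.530 (standard error 0.204 over arrays). That standard error rests on 2 residual degrees of freedom, too few to decide, so dye bias as the whole cause stays open for this list. For the granulocyte and mast cell list the mean with the dye difference taken out was 0.550 (standard error 0.348), within 2 standard errors of 0. Array 2, with the dye orientation of array 1, had 0.777 (standard error 0.240 over members), where dye bias as the whole cause would put it below 0. More blood in the IUGR samples of arrays 3 and 4 could raise both groups, but the platelet genes had a mean of 0.346 (standard error 0.152) on array 3 and 0.01 on array 4, with 9 of 14 tested (64.3%), so the test leaves it open. A difference in myeloid or mast cells with IUGR was not tested apart from this and stays open.

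The 4 arrays allow 7 assignments of IUGR and control within arrays, too few for a share under 0.05. For lists 1 of the 7 gave as many calls, the real one (real 11, highest other 9). For genes the real count was 0 (highest other 0), so each of the 7 had to give as many and the comparison decides nothing. At an unadjusted p under 0.05 the real assignment gave 2737 genes and the others gave 5275, 1038, 172, 67, 66 and 56.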

How the results depend on the processing

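Outlying backgrounds left out or kept as measured, and channel brightness as a covariate, were chosen after the data were seen. The count of 0 called genes was 15 with median centring and 7 with channel brightness, all lower; 5 were shared (Ccl21, Ccl19, Actg2, ENSRNOT00000050106 and LOC686428), and it was 0 in the other settings. The smallest adjusted p of the gene test ranged from 4.7e-06 with median centring to 0.951 without array 3. Unadjusted p under 0.05 was met by 465 genes without array 3 and 6215 without array 1. Lists called numbered 0 with an estimated correlation, 0 by fry, 9 to 14 without 1 array, and 9 to 12 in the other settings; T and NK, duct and immediate early lists were called in all 19 alternatives that kept the preset correlation, with largest adjusted p of 0.0434, 0.0257 and 0.00354. The dye count of 0 was 2 with median centring. Of the called lists, reversed were the acinar mean (-0.0018 with median centring, and from -0.057 without array 3 to 0.85 without array 4) and the ER mean (-0.075 with median centring), and with median centring 12 of all 35 list means changed sign. Of 1908 values of 87 named genes, 38 moved by more than the SD over the arrays and 19 took the other sign, and 74 genes kept 1 sign. That SD keeps the dye difference and was 1.36 for Ins1. Ins1 thus did not count as moved, though it went from 0.22 to -0.18 with median centring. Many of the 1908 values could not move. With balanced dye orientations, the ratio stays as it was under other priors, thresholds and array weights, and without the dye term. The same holds for between-array normalization, the separate-channel fit and the block by replicate number. The counts thus overstate how stable the ratios were. With the strict filter the B cell list had fewer than 5 genes. IUGR and control samples of the same replicate number had deviations from their group means that correlated at r = -0.05, -0.29, 0.08 and -0.17. Samples of the same number always carried opposite dyes, and dye bias was not taken out, so a pairing by number is not excluded. The cause of these differences was not tested. The brightness covariate stood beside the dye term and the contrast on 4 arrays, which left 1 residual degree of freedom per gene. Within a dye orientation, brightness differed most between arrays 1 and 2 (log2 IUGR over control of 1.68 and -1.58). The covariate thus mostly takes out what set array 1 apart from array 2, whatever its cause. Signal over background limits genes such as Il4 and Il13, well above background in 0 IUGR channels.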

Other observations

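The smooth muscle, defensin and lymphoid stroma lists were put together after values of some of their members were seen, so they are given as values with no p. The test of platelet genes was chosen before its result was seen.

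Smooth muscle genes were lower in IUGR islets in 13 of 13 members measured, with a mean log2 ratio of -0.72 and array means of -1.39, -0.98, -0.01 and -0.50. The enteric smooth muscle actin gene Actg2 had -1.35 ± 0.36 (SE, n = 4 arrays), with -3.46 on array 1, and the smooth muscle myosin gene Myh11 had -0.89 ± 0.19.

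Defensins and neutrophil granule peptides were higher in 8 of 10 members measured, Defa10 among them, with a mean of 0.72 and array means of -0.10, 0.49, 1.09 and 1.41. Np4 had 1.53 ± 0.27 and Defa5 had 1.47 ± 0.28 (SE, n = 4 arrays). Lymphoid stroma genes had a mean of -0.16, without Glycam1, Ccl21 and Ccl19, which were lower in IUGR and were left out because they were seen first. Platelet genes had a mean of 0.10 (camera adjusted p = 0.592).

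The GC content of the probes correlated across genes with the ratios of arrays 1 to 4 at r = 0.03, 0.23, 0.17 and 0.09.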
